A study of Arabidopsis thaliana with 18 samples.

How the data were processed

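Total RNA was extracted from about 100 mg of frozen whole seedlings per sample, turned into biotin-labelled cRNA and hybridised to Affymetrix ATH1 arrays, per the labels' protocols and the probe table. The deposited values are intensity values on a linear scale, 1 signal per probe set and array, summarised with MAS5 per the submitters' processing notes. The software version, the scaling target and any filter are not given in the sources used here. The mean without the lowest and highest 2% was 499.7 to 499.8 on every array, so the arrays had been scaled to a common trimmed mean, while the exact target and version stay unknown. The median of each array is given with the results. The values are not centred by gene and have no direction of their own. Scaling to a common trimmed mean leaves differences in the rest of the distribution, such as the higher medians at day 3, and for that reason other scalings were tried. Detection calls were not used here, and arrays carry no counting depth; their number limits the precision.

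Values were given for 22810 probe sets on 18 arrays. The 64 control probe sets were left out of all tests, and 22 signal units, the 20th percentile of all signals, were added before taking log2. Probe sets whose mean log2 signal lay above the 30th percentile were kept, which left 15922 of 22746. No further normalization was done in the main setting. Fold changes are on the log2(signal + 22) scale, so that they understate changes of dim genes. Genes were named from a probe table with GEO's platform annotation: 13513 probe sets had 1 gene, 503 had several and were not named, and 8730 other non-control probe sets had none in that table. Of the former, 13436 matched a locus of the RefSeq gene table of assembly TAIR10.1, which served for names alone, and 77 did not. Among the probe sets tested, 8711 (54.7%) had 1 gene. Coordinates are left out, because no genome build is given in the sources used here.

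Groups came from the genotype and age in the labels and replicate numbers from the titles, which call the replicates biological. The groups, tests, main settings, 16 gene lists, the rule for named genes and the alternatives, apart from those said to be added, were fixed before the data were examined. All 18 arrays entered 1 linear model with a mean for each of the 6 groups, so that all contrasts share 1 estimate of the spread. It was fitted with limma 3.58.1 (lmFit, contrasts.fit and eBayes with a mean-variance trend) in R 4.3.3, with the package data.table (version 1.17.8) to read the values and Python 3.11.15 with matplotlib 3.10.9 for figures. Contrasts were each mutant against WT and the mutants against each other at each day, day 3 against day 1 in each genotype, and the change of each mutant's difference between the days. P-values are two-sided and were adjusted by the Benjamini-Hochberg method within a contrast, and an adjusted p under 0.05 is called. For a single probe set an exact permutation test of 3 arrays against 3 cannot go below 0.1. Tested on data simulated for vte2 against WT at day 3 (15922 probe sets, 200 of them changed, 5 simulations), the fit recovered 81.6% of 4-fold and 29.2% of 2-fold changes, with 4.68% false calls. The list test found 20 of 20 shifted lists of 10 genes and 0 of 20 unchanged ones. In these simulations the noise was drawn independently for each probe set and array. Error rates where genes or same-numbered arrays correlate were therefore not tested.

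Gene lists were tested with camera at its preset correlation of 0.01, and again with the correlation estimated from the data. A list needed at least 3 measured genes, each represented by its probe set with the highest mean, and p-values were adjusted over the lists of a contrast. Of the 297 loci in the 16 lists fixed before, 40 were measured. Only 6 lists could be tested: detoxification of electrophiles and xenobiotics (7 of 37 measured), photosynthesis (6 of 34), antioxidant enzymes (4 of 28), heat shock (4 of 18), seed storage and late embryogenesis (3 of 23) and seed oil breakdown (3 of 20). The tocopherol, jasmonate, reactive oxygen, flavonoid and root marker lists had 2 measured genes each and the tryptophan, salicylic acid and cell cycle lists 1 each, and these are reported as single genes. No gene of the ethylene list or of the endosperm and seed coat marker list was measured. Because so few loci were measured, 12 lists were added after the probe annotation had been read and before any test: LEA proteins and oleosins, heat shock and chaperone loci, photosynthesis loci, detoxification loci, cytosolic ribosomal proteins, UDP-glycosyltransferases, cytochrome P450s, glutathione transferases, expansins, xyloglucan endotransglucosylases, plastid-encoded genes and 1 list that is not reported here but stayed in the adjustment. They are called wider or added lists. The first 4 hold 3, 4, 6 and 7 genes of fixed lists, and the glycosyltransferase, glutathione transferase and expansin lists 2, 3 and 2.

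Named genes were those on probe sets with 1 gene that met any of 3 conditions. For each mutant contrast and for day 3 against day 1 in WT, up to 10 higher and 10 lower genes were taken by size of log2 change among those with an adjusted p under 0.05 and all 3 values of one group beyond all 3 of the other. Of each list up to 4 called members were taken, or, if none was called, the 2 with the smallest p as values. VTE1 and VTE2 were to be named always. The text leaves some of these genes out for length.

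The titles give the same replicate numbers in every group. Deviations of same-numbered arrays from their group means correlated, for replicates 1, 2 and 3, with r = 0.35, 0.32 and 0.59 for vte1 against WT at day 1, 0.25, 0.36 and 0.55 for vte2 against WT at day 1, 0.26, 0.34 and 0.51 between the mutants at day 1, and 0.15, 0.22 and 0.37 for vte2 against WT at day 3. Those contrasts were taken as paired, a pairing that comes from the data and not from the labels, and counts with the replicate number as a block are given beside theirs.

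Alternatives were quantile normalization, centring each array on its median, a pseudocount of 5.5 or 88, no filter, a filter at the 50th percentile, eBayes without the trend, array weights, a fit on the arrays of the contrast alone, the replicate number as a block within each day, an adjusted p under 0.01, a 2-fold minimum, and leaving out each array in turn. For lists they were also the estimated correlation and the mean of a gene's probe sets. Leaving out replicate 3, 2 or 1 of all groups was added after the data were seen. For the overlap of the mutants, 100 simulations of unchanged groups that shared the WT arrays gave the chance values; a second set with the spread from the replicate block was added after the data were seen.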

Results

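Gene expression was measured in whole Arabidopsis thaliana seedlings of 3 genotypes: wild type Columbia-0 (WT) and the mutants vte1-1 and vte2-1 in the same background, called vte1 and vte2 here. Both mutants lack tocopherols, the lipid-soluble antioxidants known as vitamin E. VTE2 encodes homogentisate phytyltransferase, which makes the first committed intermediate of tocopherol synthesis, and VTE1 encodes tocopherol cyclase, which acts later in the same pathway. Seedlings were sampled after 1 or 3 days at 22 °C, following 5 days at 6 °C. Each of the 6 groups had 3 biological replicates, so that 18 Affymetrix ATH1 arrays were compared, and this number of arrays limits the precision of every value. The stated purpose was to compare the mutants with each other and with WT. VTE1 and VTE2 themselves were not analysed here, because no probe set was named for either gene in the probe table used.

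The deposited signal had nearly the same trimmed mean on all arrays (499.7 to 499.8), while its median differed. Replicates 1, 2 and 3 had median signals of 132.4, 128.9 and 148.9 in WT at day 1, 126.7, 121.8 and 143.8 in vte1 at day 1, and 135, 133.4 and 161.2 in vte2 at day 1. At day 3 the medians were 164.1, 169.7 and 167.8 in WT, 178.4, 181 and 175 in vte1, and 178.1, 174.7 and 168.8 in vte2. Replicate 3 thus had the highest median of its group in all 3 day 1 groups. Its ratio of 3' to 5' GAPDH signal, which depends on RNA integrity, was the lowest of its group in all 6 groups. On the log2 scale that ratio was 0.83, 0.56 and -0.62 in WT at day 1, 1.13, 0.56 and -0.13 in vte1, and 0.96, 0.24 and -0.23 in vte2. At day 3 it was 0.98, 0.44 and 0.06 in WT, 0.57, 1.01 and 0.43 in vte1, and 0.78, 0.67 and -0.09 in vte2. The actin ratio was also lowest in replicate 3 in all 6 groups, down to 2.7 against 4.88 and 4.74 in vte1 at day 3. The ubiquitin ratio went the other way at day 1, with 1.09, 0.94 and 1.43 in WT, 1.19, 0.94 and 1.19 in vte1 and 1.24, 0.94 and 1.32 in vte2. At day 3 it was 1.83, 1.66 and 1.83 in WT and lowest in replicate 3 in both mutants (1.22 and 1.16). Log2 signals of replicates of one group correlated with r between 0.898 and 0.977 across probe sets.

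Of 15922 probe sets tested, 333 differed between vte1 and WT at day 1 and 15 between vte2 and WT at day 1. At day 3 the corresponding numbers were 48 and 372. The mutants differed from each other in 831 probe sets at day 1 and 560 at day 3. Between day 3 and day 1, 7544 probe sets changed in WT. The means given for each gene are signals with their SD (n = 3 arrays per group), and log2 changes are differences of log2(signal + 22) with their SE, which understate the change of dim genes. Genes named for the size of their change had all 3 values of one group beyond all 3 values of the other.

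**Figure D1:**
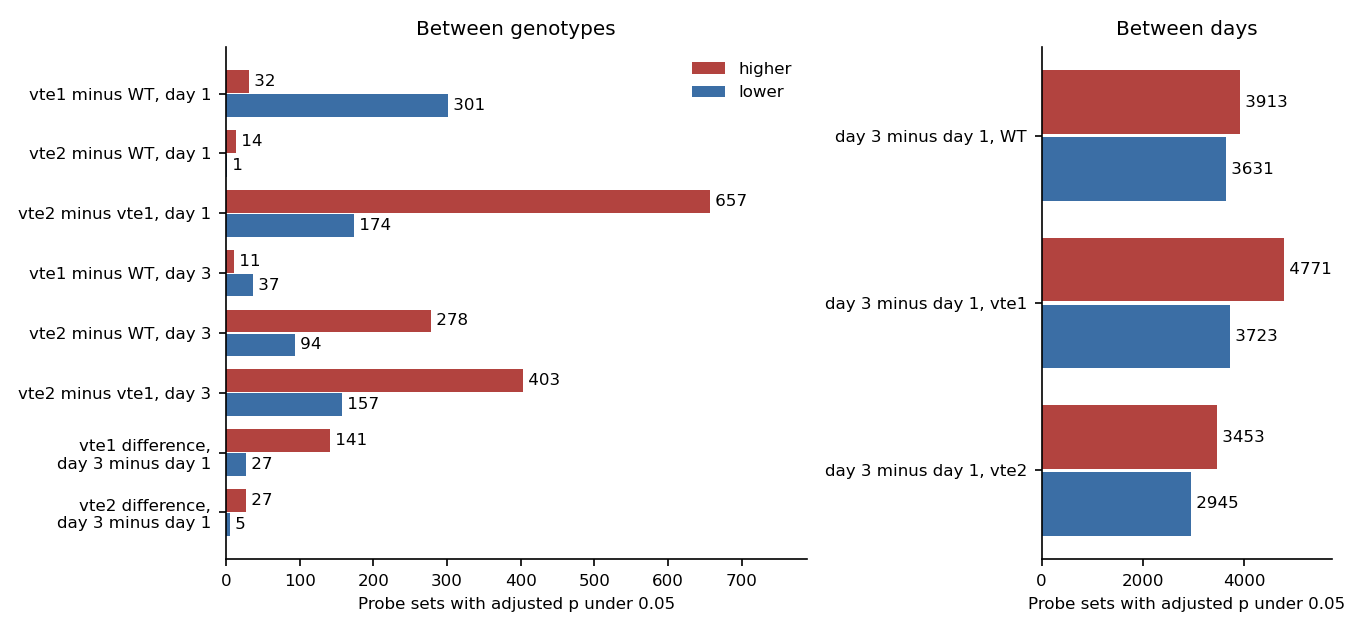
Number of probe sets (x axis) with a Benjamini-Hochberg adjusted p under 0.05 in limma for each comparison (y axis), drawn as bars for higher and lower probe sets, with comparisons between genotypes on the left and between days on the right. Between genotypes the bars total 15 to 831 probe sets, and between days 6398 to 8494.

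At day 3, vte2 seedlings carried more transcript of a lipid transfer family protein, a plant defensin, 2 oxidases and a chitinase family protein than WT. AT4G12490, of the lipid transfer protein family, had a signal of 4234 ± 1074 against 50.1 ± 24.0 in WT, a log2 change of 5.92 ± 0.47 (adjusted p = 5.8e-07). The plant defensin gene PDF1.4 reached 4931 ± 608 against 102 ± 40.6 (5.37 ± 0.39, adjusted p = 2.5e-07), and AT1G65500 reached 1265 ± 357 against 4.8 ± 1.49 (5.55 ± 0.38, adjusted p = 1.3e-07). The berberine bridge enzyme-like oxidase genes AT1G26380 and AT1G26420 rose by 4.30 ± 0.60 and 4.05 ± 0.65 on the log2 scale, the chitinase family gene AT2G43620 by 4.14 ± 0.57, and the class III peroxidase gene PRX52 by 3.73 ± 0.55 (adjusted p = 3e-04 to 0.0013). AT1G56060, AT1G13340 and AT2G32190 rose by 4.52, 3.83 and 3.68. On the lower side, the glutaredoxin family gene AT3G62950 had 242 ± 88.8 against 1210 ± 499 (-2.17 ± 0.40, adjusted p = 0.0046), and the late embryogenesis abundant (LEA) gene AT4G21020 had 4.2 ± 1.68 against 96.0 ± 9.02 (-2.17 ± 0.48, adjusted p = 0.017). In the plot of signals per array, replicates 1, 2 and 3 of vte2 lay at 5413.7, 3975.3 and 3312.2 for AT4G12490 and at 4283.2, 5020.6 and 5489 for PDF1.4. The 10 higher genes named here kept their call in every alternative run for single genes, while AT3G62950 and AT4G21020 lost it in some (highest adjusted p = 0.074 and 0.071). Leaving a replicate out of all groups was not run for single genes.

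Several genes for the detoxification of electrophiles were higher in vte2 than in WT at day 3. Of the 7 measured members of the detoxification list fixed before the data were examined, 2 rose, and 5 rose when adjusted over the list alone. The median change was 0.69 (camera adjusted p = 0.00028, and adjusted p = 0.034 with an estimated correlation). The glutathione transferase gene GSTU25 rose from 453 ± 175 to 1559 ± 624 (1.74 ± 0.30, adjusted p = 0.0028) and the glycosyltransferase gene UGT73B4 from 150 ± 8.36 to 532 ± 208 (1.62 ± 0.40, adjusted p = 0.035). In a wider list of 16 detoxification loci, which shares all 7 of these, 5 rose and none fell. They were GSTU25 and UGT73B4 again, the oxidase genes AT1G26380 and AT1G26420 named above, and the efflux carrier gene AT1G71140 (2.2 ± 0.41, adjusted p = 0.0047). The median of that list was 0.95 (adjusted p = 1.8e-09, and 0.034 with an estimated correlation). The lists of 11 glutathione transferases (median 0.21, camera adjusted p = 0.17) and 11 cytochrome P450s (median 0.06, camera adjusted p = 0.51) had no call. Of 36 measured UDP-glycosyltransferase genes 4 rose and none fell (median 0.32, adjusted p = 0.00028, and 0.034 with an estimated correlation). UGT76E12, UGT87A2 and UGT74B1 were among them at 1.65, 1.15 and 0.90. UGT74B1 lost its call after quantile normalization (adjusted p = 0.061) and median centring (0.11), among others, and kept it in 5 of 16 alternatives. UGT76E12 kept it in 10 of 15 (0.79 to 2.49, adjusted p up to 0.18), UGT73B4 in 11 of 16 (up to 0.19) and UGT87A2 in 15 of 16 (up to 0.057). UPOX (AT2G21640), a marker of oxidative stress in mitochondria and 1 of 2 measured members of the reactive oxygen list, rose from 85.0 ± 66.8 to 537 ± 110 (2.54 ± 0.49, adjusted p = 0.0062). AT2G04400, indole-3-glycerol phosphate synthase of tryptophan synthesis and the single measured member of its list, rose from 528 ± 62.1 to 1808 ± 381 (1.72 ± 0.23, adjusted p = 0.00018). Between day 1 and day 3 in WT, GSTU25, UGT73B4, UGT76E12, UPOX and AT2G04400 fell, by -2.32, -1.01, -3.5, -2.24 and -1.65. AT1G26380 was low in WT at both days (108.8, 35.7 and 82.6, then 63.7, 3.4 and 83). The WT arrays of day 3 enter both differences, and a difference in stage was not tested for single genes.

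Photosynthesis transcripts were lower in vte2 than in WT at day 3, by amounts that depended on the scaling. In the list fixed before, 1 of 6 members fell, and 2 fell when adjusted over the list alone, with a median of -0.75 (camera adjusted p = 0.00021, and adjusted p = 0.15 with an estimated correlation); after quantile normalization the median was -0.15 and the call was lost (adjusted p = 0.37). Of 12 members of a wider photosynthesis list that holds those 6, 4 fell and none rose. Their median was -0.76 (adjusted p = 5.5e-10, and 0.034 with an estimated correlation), or -0.27 (adjusted p = 0.017) after quantile normalization. The photosystem II assembly gene PSB27 fell from 27430 ± 5201 to 14160 ± 2810 (-0.95 ± 0.21, adjusted p = 0.016), and AT1G51400, PSBW and AT2G26500 had changes of -0.78, -0.77 and -0.74, but after quantile normalization these 4 genes stood at -0.46, -0.42, -0.37 and -0.18 and were no longer called (adjusted p = 0.21 to 0.68). The small heat shock protein gene AT2G29500 rose from 243 ± 82.4 to 1939 ± 121 (2.93 ± 0.43, adjusted p = 0.00059). It was the only one of 4 members of the heat shock list to pass (median 0.25, adjusted p = 0.12). In a wider list of 8 chaperone loci that holds those 4, 2 rose and none fell (median 0.60, adjusted p = 0.0068, and 0.15 with an estimated correlation). None of the 4 measured antioxidant enzyme genes passed (median -0.49, adjusted p = 0.20), although 1 was higher and 2 were lower when adjusted over the list alone. TAPX, the thylakoid ascorbate peroxidase gene, had 1571 ± 770 against 2966 ± 595 (-1.03, adjusted p = 0.12, or 0.047 with the replicate as a block).

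In total 372 probe sets differed between vte2 and WT at day 3, 278 higher and 94 lower, and 295 of them at least 2-fold. With the replicate number as a block there were 834 calls (572 higher and 262 lower), which included all 372. With 1 array left out the count was 244, 177 or 294 (WT replicate 1, 2 or 3) and 212, 231 or 183 (vte2 replicate 1, 2 or 3). With replicate 3 left out of all groups it was 1200, with replicate 2 left out 40 and with replicate 1 left out 43. All 3 values of vte2 lay beyond all 3 values of WT in 19.8% of the probe sets, against 10% by chance. That 10%, here and below, holds for arrays without pairing and is not exact where the arrays were taken as paired. The smallest two-sided exact permutation p that 3 arrays against 3 allow is 0.1.

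**Figure D2:**
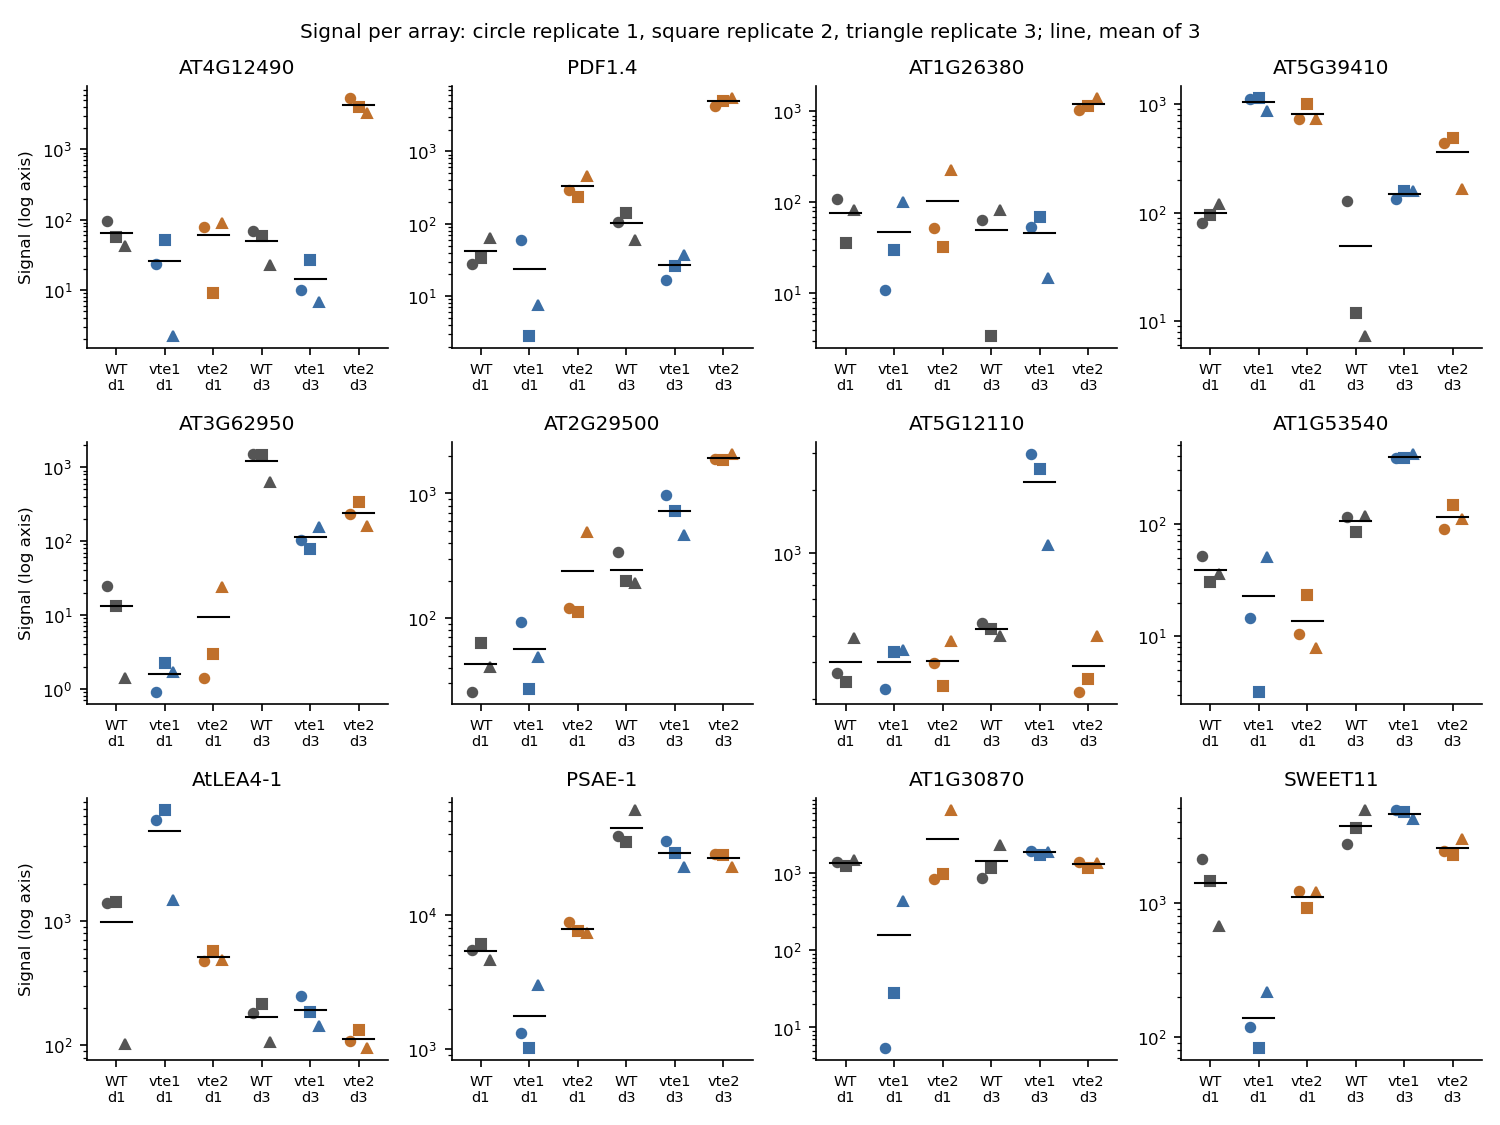
Signal per array (y axes, log scale, MAS5 signal units) of 12 named genes in the 6 groups (x axes), with a circle, square and triangle for replicates 1, 2 and 3 and a line at the mean of the 3 arrays. AT4G12490 and PDF1.4 stand highest in vte2 at day 3, at means of 4234 and 4931, and PSAE-1, AT1G30870 and SWEET11 stand lowest in vte1 at day 1, at means of 1779, 158 and 140.

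At day 1, 4 LEA genes were among the genes higher in vte1 than in WT, and SWEET11 and 4 class III peroxidase genes among those lower. Of the named genes that passed, AT5G39410 rose most, at 1037 ± 158 against 98.5 ± 20.4 in WT (3.14 ± 0.46, adjusted p = 0.001). The LEA genes AT3G17520, AtLEA4-1, AT4G21020 and AT2G21490 rose by 3.08 ± 0.75, 2.74 ± 0.69, 2.27 ± 0.48 and 1.79 ± 0.41 (adjusted p = 0.014 to 0.04). The vacuolar processing enzyme gene BETA-VPE, whose product matures seed storage proteins, rose from 734 ± 216 to 2453 ± 1054 (1.64 ± 0.35, adjusted p = 0.015). Among the lower genes, SWEET11, a sucrose efflux transporter gene, fell from 1406 ± 711 to 140 ± 69.1 (-3.08 ± 0.34, adjusted p = 8.6e-05) and AT4G22490 from 1408 ± 132 to 209 ± 159 (-2.83 ± 0.35, adjusted p = 0.00026). The class III peroxidase genes AT1G30870, AT3G49960, AT5G51890 and AT3G01190 fell, with log2 changes of -4.03, -3.52, -3.03 and -2.78 (adjusted p = 0.0024 to 0.031). EXPA7, a root hair expansin gene and a member of the root marker list, fell from 633 ± 164 to 98.7 ± 127 (-2.93 ± 0.65, adjusted p = 0.02). AT1G74470, the geranylgeranyl reductase that supplies the phytyl chain of chlorophyll and tocopherol, fell from 8177 ± 998 to 2548 ± 2227 (-2 ± 0.36, adjusted p = 0.0044).

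The photosynthesis list was lower in vte1 at day 1, with 2 of 6 members called lower, 6 when adjusted over the list alone, and 4 with the replicate as a block. Its median was -1.20 (camera adjusted p = 5.2e-08, and adjusted p = 0.087 with an estimated correlation). The photosystem I genes PSAE-1 and PSAN fell from 5416 ± 742 to 1779 ± 1060 (-1.74 ± 0.30, adjusted p = 0.0033) and from 1772 ± 345 to 644 ± 381 (-1.57 ± 0.33, adjusted p = 0.014). In the wider list of 12 loci 2 fell, with a median of -0.78 (adjusted p = 1.6e-10, and 0.087 with an estimated correlation). LEA protein and oleosin genes went the other way: 3 of 11 rose and none fell, with a median of 2.12 (adjusted p = 8e-09, and 0.22 with an estimated correlation). Of the 3 measured members of the seed storage list, which are also in that wider list, none passed, while 2 were higher when adjusted over the list alone (median 2.92, adjusted p = 0.045, and 0.55 with an estimated correlation). LEA4-5 had 8196 ± 5732 against 1344 ± 1075 (2.92, adjusted p = 0.07, or 7e-04 with the replicate as a block). That seed storage call was lost after quantile normalization (adjusted p = 0.051) and after median centring (0.068). It was also lost without WT replicate 3 (median 1.59, adjusted p = 0.82) or vte1 replicate 1, 2 or 3 (adjusted p = 0.058, 0.11 and 0.062). Replicate 3, with the lowest GAPDH 3' to 5' ratio, stood apart in vte1 and WT for AtLEA4-1, and in vte1 for PSAE-1. AtLEA4-1 read 6510.7, 7803.2 and 1472.8 in vte1 and 1394.8, 1431.7 and 102.5 in WT. PSAE-1 read 1330.1, 1017.4 and 2989.2 in vte1 against 5465.2, 6132.7 and 4651.3 in WT.

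In total 333 probe sets differed between vte1 and WT at day 1, 32 higher and 301 lower. With the replicate number as a block there were 754 (148 higher and 606 lower), which included 332 of the 333. Leaving out 1 array gave 131, 160 or 190 (WT replicate 1, 2 or 3) and 106, 111 or 1061 (vte1 replicate 1, 2 or 3). With replicate 3 left out of all groups the count was 2148, and with replicate 1 or replicate 2 left out it was 0, where 737 and 749 probe sets had an unadjusted limma p under 0.05. The fit on the 6 arrays of the comparison alone called 17. Single genes were not run with a replicate left out of all groups, and without replicate 1 or replicate 2 no probe set was called. Of the alternatives run for single genes, AT5G39410 kept its call in every one, and SWEET11 and AT4G22490 in 15 of 16 each (highest adjusted p = 0.067). AT5G51890, AT1G74470 and PSAE-1 also kept it in 15 of 16, but with adjusted p up to 0.19. Others lost it more often: AT1G30870 kept it in 13 of 16, AtLEA4-1, EXPA7, PSAN and BETA-VPE in 11 of 16, AT3G01190 in 10 of 16, AT3G49960 in 9 of 16, and AT4G21020 and AT2G21490 in 10 of 15. AtLEA4-1 went as low as 1.56 (highest adjusted p = 0.39). AT3G17520 kept it in 7 of 15 and lost it after quantile normalization, among others (adjusted p = 0.057). No overlap between the groups was seen in 15.3% of the probe sets (10% by chance).

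At day 1, vte2 differed from WT in 15 probe sets, 14 higher and 1 lower, of which 6 had a named gene. AT5G39410, also higher in vte1, rose from 98.5 ± 20.4 to 814 ± 159 (2.79 ± 0.46, adjusted p = 0.012). PDF1.4 was higher than in WT at this day too, at 328 ± 116 against 41.8 ± 19.1 (2.45 ± 0.39, adjusted p = 0.012), and so was AT2G32190, at 1152 ± 946 against 133 ± 45.6 (2.67 ± 0.42, adjusted p = 0.011). The pirin gene PRN rose from 83.8 ± 12.4 to 489 ± 223 (2.19 ± 0.36, adjusted p = 0.013), and AT5G22580 and AT5G10695 rose by 2.04 ± 0.35 and 1.81 ± 0.31. Each of these 6 genes lost its call in at least 1 alternative (highest adjusted p = 0.093 to 0.41). No member of any list passed singly. The detoxification list had a median of 0.48 with 1 member higher when adjusted over the list alone (camera adjusted p = 0.0058, and adjusted p = 0.16 with an estimated correlation). The photosynthesis list had a median of 0.34 with none (0.0058, and 0.42 with an estimated correlation). Both list calls were lost without vte2 replicate 3 (median 0.30 and 0.22, adjusted p = 0.12 for each). So was that of the wider detoxification list (from 0.46, adjusted p = 0.00029, and 0.30 with an estimated correlation, to 0.16, adjusted p = 0.38). With the replicate number as a block the 15 calls became 31 (25 higher and 6 lower) and included all 15. With any 1 array removed there were 5, 6 or 14 (WT replicate 1, 2 or 3) and 18, 10 or 11 (vte2 replicate 1, 2 or 3). With replicate 3, 2 or 1 left out of all groups there were 72, 0 and 2, where the 0 stands beside 276 probe sets at an unadjusted limma p under 0.05. Groups did not overlap in 9.22% of the probe sets (10% by chance without pairing, while these arrays were taken as paired).

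At day 3, vte1 seedlings had more heat shock protein transcripts than WT. Of the 4 measured members of the heat shock list 1 rose, and all 4 rose when adjusted over the list alone, with a median of 1.60 (camera adjusted p = 1.1e-06, and adjusted p = 0.0021 with an estimated correlation). In the wider list of 8 chaperone loci 2 rose and none fell (median 1.46, adjusted p = 1.8e-11, and 0.0021 with an estimated correlation). The small heat shock protein genes AT5G51440, of mitochondria, and AT1G53540 rose from 116 ± 24.5 to 623 ± 325 (2.08 ± 0.38, adjusted p = 0.028) and from 105.3 ± 18.21 to 396 ± 19.5 (1.72 ± 0.35, adjusted p = 0.04). AT5G12110, a translation elongation factor gene, rose from 434 ± 30.7 to 2197 ± 982 (2.17 ± 0.33, adjusted p = 0.008), and AT3G22260 and AT1G30070 rose by 1.86 ± 0.32 and 1.43. The glutaredoxin gene AT3G62950 fell from 1210 ± 499 to 113 ± 39.5 (-3.13 ± 0.40, adjusted p = 0.0036). AKINBETA1, a regulatory subunit gene of the energy-sensing SnRK1 kinase, fell from 2697 ± 1103 to 1008 ± 477 (-1.41, adjusted p = 0.048), and ALDH6B2 from 5721 ± 2296 to 2127 ± 403 (-1.34, adjusted p = 0.032). AT1G25400 and AT1G56220 fell, with changes of -2.57 and -1.77.

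Other groups moved less in vte1 at day 3. The photosynthesis list had a median of -0.54 with no member passing and 1 lower when adjusted over the list alone (camera adjusted p = 0.002, and adjusted p = 0.25 with an estimated correlation), a call lost after quantile normalization (-0.06, adjusted p = 0.52) and without WT replicate 3 (-0.36, adjusted p = 0.071). The wider list likewise went from -0.36 (adjusted p = 1.2e-05, and 0.16 with an estimated correlation) to -0.07 (adjusted p = 0.50) after quantile normalization. The 3 measured genes of seed oil breakdown had a median of -0.81 with none passing and 2 lower when adjusted over the list alone (adjusted p = 0.0091, and 0.16 with an estimated correlation). The detoxification list had a median of 0.42 with 1 member higher and 1 lower over the list alone (adjusted p = 0.70), and the antioxidant list one of 0.17 (adjusted p = 0.32). In total 48 probe sets differed, 11 higher and 37 lower. With any 1 array removed the count was 6, 7 or 337 (WT replicate 1, 2 or 3) and 2, 4 or 134 (vte1 replicate 1, 2 or 3). With replicate 3 left out of all groups it was 1906, and with replicate 1 or replicate 2 left out 0, where 596 and 564 probe sets had an unadjusted limma p under 0.05. AT3G62950 kept its call in every alternative run for single genes, while each of the other genes named here lost it in some. Those runs did not leave a replicate out of all groups, where 0 probe sets were called without replicate 1 or replicate 2. Groups did not overlap in 16.9% of the probe sets (10% by chance).

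**Figure D3:**
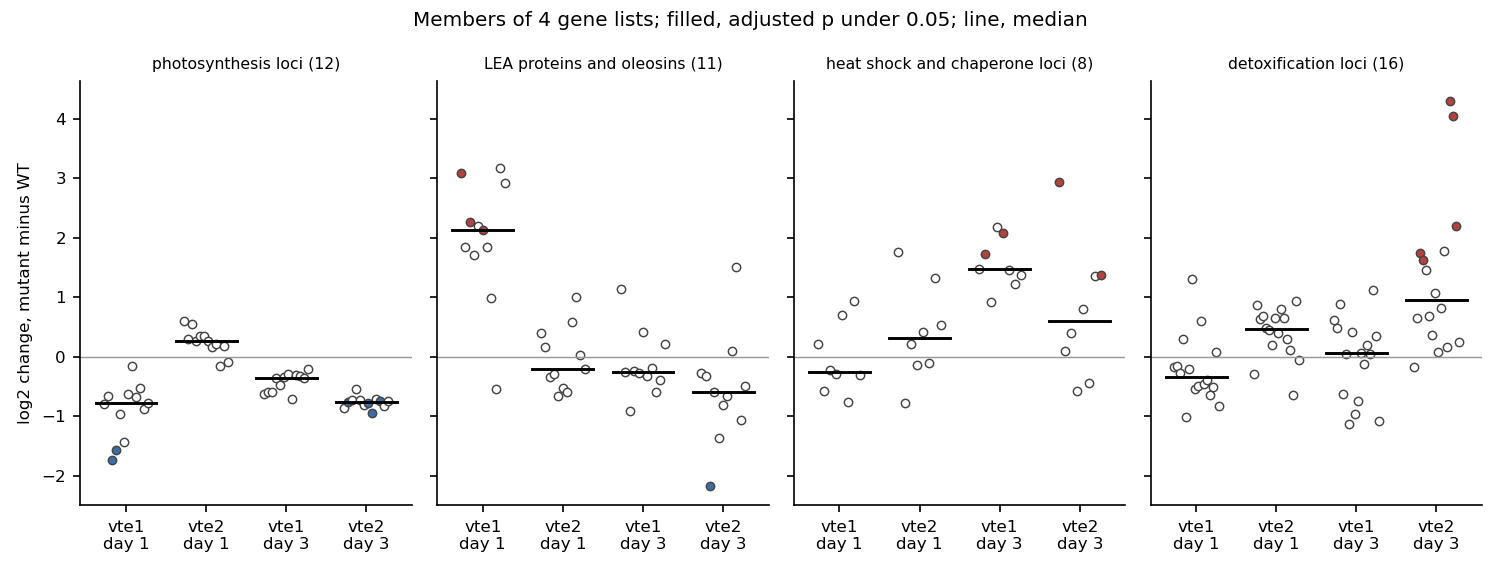
Log2 change of each measured gene (points) of the photosynthesis, LEA and oleosin, heat shock and chaperone, and detoxification lists (12, 11, 8 and 16 genes) for vte1 or vte2 minus WT at day 1 or day 3 (x axis), with a line at the list's median and filled points for an adjusted p under 0.05. The medians are -0.78 for photosynthesis and 2.12 for LEA genes in vte1 at day 1, 1.46 for chaperones in vte1 at day 3 and 0.95 for detoxification in vte2 at day 3; the photosynthesis medians at day 3, -0.36 in vte1 and -0.76 in vte2, shrink to -0.07 and -0.27 after quantile normalization.

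Set against each other at day 1, the mutants differed in photosynthesis and late embryogenesis genes. All 6 members of the photosynthesis list were higher in vte2 than in vte1 when adjusted over the list alone and 5 among all probe sets tested, with a median of 1.59 (camera adjusted p = 6.9e-09, and adjusted p = 0.06 with an estimated correlation). PSAE-1 had 7944 ± 824 in vte2 against 1779 ± 1060 in vte1 (2.30 ± 0.30, adjusted p = 0.00013), and PSAN, PRK and LHCB4.1 were higher by 1.83, 1.78 and 1.39. In the wider list 7 of 12 rose (median 1.01, adjusted p = 3.6e-11, and 0.06 with an estimated correlation). Of 11 LEA and oleosin genes 5 were lower in vte2 than in vte1 and none higher (median -2.60, adjusted p = 4.5e-07, and 0.29 with an estimated correlation). AtLEA4-1 had 513 ± 55.4 against 5262 ± 3345 (-2.99 ± 0.69, adjusted p = 0.013), LEA4-5 683 ± 198 against 8196 ± 5732 (-3.13 ± 0.80, adjusted p = 0.027), and BETA-VPE 330 ± 118 against 2453 ± 1054 (-2.76 ± 0.35, adjusted p = 1e-04). The seed storage list had 1 member lower (2 lower and 1 higher over the list alone; median -3.13, adjusted p = 0.17). The root marker genes EXPA7 and EXPA18 were higher in vte2 by 3.01 and 2.56 (adjusted p = 0.0085 and 0.028). So were AT1G30870 (2832 ± 3322 against 158 ± 245, adjusted p = 0.0015), PDF1.4 (3.11 ± 0.39, adjusted p = 1e-04) and AT1G74470 (1.98, adjusted p = 0.0023). For AT1G30870 replicate 3 stood apart in both groups, at 6667.7 against 852 and 976 in vte2 and at 440.6 against 5.4 and 28.2 in vte1.

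The detoxification list had 1 member higher in vte2 than in vte1 at day 1, and 3 when adjusted over the list alone (median 0.64, adjusted p = 0.083). The wider detoxification list was called (median 0.76, camera adjusted p = 0.0025), but not with an estimated correlation. Its call was also lost without vte2 replicate 3 (median 0.49, camera adjusted p = 0.11). In total 831 probe sets differed, 657 higher and 174 lower in vte2, and 1709 with the replicate number as a block (1196 higher and 513 lower, with all 831 kept). Leaving out 1 array gave 382, 370 or 1854 (vte1 replicate 1, 2 or 3) and 645, 635 or 408 (vte2 replicate 1, 2 or 3). With replicate 3, 2 or 1 left out of all groups there were 2923, 49 and 102, and with the 6 arrays of the comparison alone 102. Groups did not overlap in 18.9% of the probe sets (10% by chance).

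At day 3, vte2 also exceeded vte1 in several of the genes that were higher than in WT. AT4G12490 and PDF1.4 were higher by 6.88 ± 0.47 and 6.69 ± 0.39 (adjusted p = 8.7e-08 and 1.1e-08), AT2G43620 by 4.88, AT1G26380 by 4.25 and PRX52 by 3.99. The lectin gene AT3G16530 had 2949 ± 999 in vte2 against 270 ± 29.3 in vte1 (3.30, adjusted p = 0.0025). AER, an alkenal reductase gene whose product removes reactive aldehydes, had 2049 ± 49.5 against 569 ± 109 (1.82 ± 0.30, adjusted p = 0.0014). In the detoxification list 2 of 7 rose and none fell, 4 higher and 1 lower when adjusted over the list alone (median 0.86, camera adjusted p = 0.0063, and adjusted p = 0.073 with an estimated correlation). In the wider list 6 of 16 rose (median 1.37, adjusted p = 8.5e-10, and 0.073 with an estimated correlation). Of the genes lower in vte2, AT5G12110 had 289 ± 98.6 against 2197 ± 982 (-2.76 ± 0.33, adjusted p = 6.9e-05) and the immunophilin gene AT5G48570 272 ± 54.6 against 2092 ± 889 (-2.76 ± 0.49, adjusted p = 0.003). Of the heat shock list 2 of 4 were lower in vte2 (median -1.07, adjusted p = 0.052; 2 lower and 1 higher over the list alone), including AT1G53540 (-1.62, adjusted p = 0.013). Of the wider list 3 of 8 were lower (median -0.90, adjusted p = 0.015, and 0.16 with an estimated correlation). That list call was lost without the filter (-0.43, adjusted p = 0.071), with the stricter filter (-0.51, adjusted p = 0.18) and without vte1 replicate 1 (-0.67, adjusted p = 0.06). ICL, isocitrate lyase of the glyoxylate cycle that uses seed oil, was higher in vte2, at 12620 ± 1255 against 2541 ± 1853 (2.53 ± 0.46, adjusted p = 0.0037). It was the 1 member called of a seed oil list of 3 (1 over the list alone, median 0.56, adjusted p = 0.0063, and 0.10 with an estimated correlation). TAPX was lower (-1.25, adjusted p = 0.037), 1 of 4 antioxidant genes (2 lower over the list alone; median -0.62, adjusted p = 0.047, and 0.16 with an estimated correlation). The antioxidant list call was lost in several alternatives, among them the block (adjusted p = 0.061) and without vte1 replicate 1 or 2 or vte2 replicate 3 (0.06, 0.065 and 0.067). The fixed detoxification list lost its call without vte2 replicate 3 and with array weights (0.067 and 0.069). TAPX kept its call in 8 of 16 alternatives and AT1G53540 in 11 of 15.

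In total 560 probe sets differed between vte2 and vte1 at day 3, 403 higher and 157 lower in vte2. Leaving out 1 array gave 259, 246 or 460 (vte1 replicate 1, 2 or 3) and 333, 281 or 594 (vte2 replicate 1, 2 or 3). With replicate 3, 2 or 1 left out of all groups there were 2229, 33 and 29. Groups did not overlap in 25% of the probe sets (10% by chance).

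The changes of vte1 and vte2 against WT showed little overlap at day 1. AT5G39410 was the 1 probe set called higher in both mutants, against 0.0281 for independent lists, and none was called lower in both. Across probe sets the log2 changes of the mutants correlated with r = -0.0133 (jackknife SE 0.295), where 100 simulations of unchanged groups that share the WT arrays gave r = 0.50. The covariance was -0.00219 against 0.0674 simulated, a difference of -0.0696, or of -0.049 from the 0.0468 simulated with the spread left by the replicate as a block. At day 3, 5 probe sets were called higher in both mutants (0.192 for independent lists) and 2 lower in both (0.218 for independent lists), among them AT3G62950, AT3G22260 and AT1G30070. There r was 0.316 (jackknife SE 0.2) and the covariance 0.0724, which exceeded the simulated value by 0.00503, or by 0.0256 with that smaller spread. The simulations used 1 spread pooled over both days, so the simulated covariance was the same at each day. A spread that differs between the days was not simulated. Effects shared by same-numbered arrays cancel in differences between groups, so the first simulation overstates the chance covariance where the numbers pair the arrays. The 3 WT arrays of a day were too few to split, so part of any excess may come from the shared controls. Of the 372 day 3 calls in vte2, 75.3% had the same sign in vte1, and of the 48 calls in vte1, 87.5% had the same sign in vte2. For as many of the most extreme probe sets of the simulated unchanged groups these shares were 93.3% and 96.5%. At day 1 the shares were 73.3% of 15 and 29.1% of 333, with 97.9% and 93.2% simulated. The simulated groups held noise alone, and their most extreme probe sets share a sign through the shared WT arrays. Where the called probe sets also hold real changes, the simulated shares are no chance level for them, and no conclusion is drawn from the gap. Genes are not independent replicates in these correlations and shares.

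Between day 1 and day 3, photosynthesis transcripts rose and ribosomal protein transcripts fell in WT seedlings. All 6 members of the photosynthesis list and all 12 of the wider list rose, and so did all 6 of the fixed list when adjusted over the list alone, with medians of 3.52 (camera adjusted p = 3.9e-06, and adjusted p = 0.19 with an estimated correlation) and 3.17 (4.7e-11, and 0.091 with an estimated correlation). PSAN rose from 1772 ± 345 to 30180 ± 7063 (4.07 ± 0.33, adjusted p = 1.5e-08) and RCA, the Rubisco activase gene, from 5109 ± 1484 to 59170 ± 9580 (3.55, adjusted p = 5.4e-07). All 63 measured cytosolic ribosomal protein genes fell, with a median of -1.73 (adjusted p = 1.1e-25, and 0.23 with an estimated correlation). The serine carboxypeptidase-like genes scpl44, scpl35 and scpl20 fell, with log2 changes of -5.69 ± 0.46, -5.27 ± 0.23 and -5.25 ± 0.31. ICL fell from 35760 ± 6158 to 7506 ± 4612 (-2.53 ± 0.46, adjusted p = 0.00018). CCL, a clock-regulated gene, rose by 7.55 ± 0.56, AT1G22690 by 7.35 ± 0.35 and AT3G05730 by 7.06 ± 0.30. TAPX rose from 121 ± 23.8 to 2966 ± 595 (4.37, adjusted p = 4.9e-09), in an antioxidant list with 2 members higher and 2 lower, also over the list alone (median 0.08, adjusted p = 0.81). Heat shock genes (3 higher and 1 lower of 4, the same over the list alone, adjusted p = 0.77), detoxification genes (3 lower of 7, 3 over the list alone, adjusted p = 0.29), seed oil genes (1 lower of 3, 1 over the list alone, adjusted p = 0.81) and seed storage genes (none of 3, none over the list alone, median -1.60, adjusted p = 0.49) had no list call.

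In total 7544 probe sets differed between the days in WT (3913 higher and 3631 lower), 8494 in vte1 (4771 and 3723) and 6398 in vte2 (3453 and 2945). The groups did not overlap in 55.2%, 58.6% and 51.8% of the probe sets, against 10% by chance. In vte1 the median log2 difference between day 3 and day 1 over all probe sets was 0.137 as deposited and -0.128 after quantile normalization, and the share of higher calls went from 56.2% to 45.3% (44.6% after median centring). The same share went in WT from 51.9% to 45.5% and 46.1%, and in vte2 from 54.0% to 46.2% and 44.5%. All 12 members of the wider photosynthesis list rose in both mutants as well, with medians of 3.74 in vte1 (adjusted p = 5.7e-10, and 0.13 with an estimated correlation) and 1.93 in vte2 (adjusted p = 6e-09, and 0.18 with an estimated correlation). The 11 LEA and oleosin genes all fell in vte1 (median -2.83, adjusted p = 0.00026, and 0.35 with an estimated correlation), a list call lost with the stricter filter (median -4.91, adjusted p = 0.09). With replicate 2 left out of all groups the counts were 4648 in WT, 5566 in vte1 and 3022 in vte2, and with replicate 1 left out 4776 in WT and 3384 in vte2.

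Whether a mutant's difference from WT changed between the days was tested directly as an interaction. For vte1, 168 probe sets passed, 141 with a higher difference at day 3 and 27 with a lower one (614 with the replicate number as a block). For vte2 32 passed, 27 and 5 (71 with the block). SWEET11 and AT1G30870, low in vte1 at day 1, had interactions of 3.41 ± 0.48 (adjusted p = 0.0033) and 4.51 ± 1.08 (adjusted p = 0.049). AT4G12490 and AT1G65500 had interactions in vte2 of 6.16 ± 0.67 (adjusted p = 0.00017) and 5.36 ± 0.53 (adjusted p = 7.8e-05). Leaving out 1 array made the vte1 count range from 33 (without WT replicate 2 of day 3) to 637 (without vte1 replicate 3 of day 1), and the vte2 count from 6 to 43. With replicate 3 left out of all groups the counts were 2142 and 316. With replicate 2 left out they were 0 and 1, and with replicate 1 left out both were 0. In limma 770 (vte1 without replicate 2), 850 (vte1 without replicate 1) and 599 (vte2 without replicate 1) probe sets then had an unadjusted p under 0.05.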

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

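The tests of replicate 3, of the array scaling and of the splits that part the pairs were chosen after the results were seen; the tests of developmental stage and of the other splits of the arrays were written before. The results in this part stand out because a mutant's difference from WT changed between day 1 and day 3, by the interaction term in limma.

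In vte1 the difference from WT changed for 168 probe sets. AT1G30870 and AT5G51890, class III peroxidase genes, were lower than in WT at day 1 (-4.03 and -3.03) and near WT at day 3 (0.48 and 0.40), with interactions of 4.51 ± 1.08 (adjusted p = 0.049) and 3.43 ± 0.71 (adjusted p = 0.023). SWEET11 went from -3.08 to 0.33 (3.41 ± 0.48, adjusted p = 0.0033) and AT4G22490 from -2.83 to -0.35 (2.49 ± 0.50, adjusted p = 0.021). The LEA gene AT4G21020 went from 2.27 to -0.92 (-3.18 ± 0.67, adjusted p = 0.027). AT5G12110 went from 0 to 2.17 (2.16 ± 0.46, adjusted p = 0.027) and the small heat shock gene AT1G53540 from -0.57 to 1.72 (2.30 ± 0.50, adjusted p = 0.029). AT3G62950 went from -0.52 to -3.13 (-2.62 ± 0.56, adjusted p = 0.028), AT1G56220 from 1.13 to -1.77 (-2.90 ± 0.47, adjusted p = 0.0097) and AT3G47800 from 0.30 to -1.42 (-1.72 ± 0.39, adjusted p = 0.039). As lists, heat shock genes went from a median of -0.26 to 1.60 (interaction 1.77, adjusted p = 0.00017, and 0.026 with an estimated correlation) and the wider chaperone list from -0.26 to 1.46 (interaction 1.52, adjusted p = 5e-06, and 0.031 with an estimated correlation). Only 1 of 100 splits within days, the real one, called as many probe sets in the fit on these arrays (159, the next highest 57). A random grouping of the arrays thus seldom gives such a count. The splits mix the genotypes within each day, so they do not test against a difference from WT that is the same at both days. With replicate 1 or replicate 2 left out of all groups the count was 0. Among the 80 splits that part the same-numbered pairs of day 1, the real one was again the highest, with 57 for the next.

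In vte2 the difference from WT changed for 32 probe sets. AT4G12490 went from -0.24 at day 1 to 5.92 at day 3 (6.16 ± 0.67, adjusted p = 0.00017) and AT1G65500 from 0.19 to 5.55 (5.36 ± 0.53, adjusted p = 7.8e-05). The oxidase genes AT1G26380 and AT1G26420 had interactions of 4.19 ± 0.85 (adjusted p = 0.048) and 4.69 ± 0.92 (adjusted p = 0.036). PRX52 had one of 4.44 ± 0.77 (adjusted p = 0.018) and the chitinase family gene AT2G43620 of 4.11 ± 0.81 (adjusted p = 0.039). PDF1.4, higher than in WT at both days, went from 2.45 to 5.37 (2.92 ± 0.56, adjusted p = 0.033). The wider photosynthesis list went from a median of 0.26 to -0.76 (interaction -1.05, adjusted p = 5.5e-13, and 0.048 with an estimated correlation). After quantile normalization its day 3 median was -0.27 and the interaction -0.62 (adjusted p = 7.7e-05). Here 9 of 100 splits called as many probe sets as the real one (14 in the fit on these arrays, against 265 for the highest other), so that a random grouping cannot be excluded for the count. The other 8 all kept the vte2 and WT arrays of day 3 apart and mixed or swapped those of day 1, so that the day 3 difference between the genotypes enters their counts. Of the 32 splits that part every same-numbered pair at both days, 6 called as many (the highest other 203). With the replicate as a block the real one called 126 and 5 of 32 called as many (the highest other 622). These others, too, all kept the day 3 genotypes apart.

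A first pattern is the set of 333 probe sets called between vte1 and WT at day 1, which a slower germination of the vte1 seedlings could produce. Of these probe sets, 64.6% moved the opposite way between day 1 and day 3 in vte2, whose arrays are not part of that comparison, against 57.6% of the probe sets not called. The share lies between the bounds set beforehand, so that a difference in stage and a direct effect of the genotype cannot be told apart. With replicate 3 of all groups left out there were 2148 calls, which include 330 of the 333, so that these 330 did not need replicate 3. The number of calls rose in every comparison between genotypes without replicate 3, so that it does not decide on replicate 3 as a cause. With replicate 1 or replicate 2 left out of all groups it was 0 for this comparison. The array scaling as the whole cause is argued against by the 260 calls after quantile normalization, 255 of them among the 333. The 10 splits of these 6 arrays are too few for a share under 0.05. The real one, 1 of 10, called 17 and the highest other 0, where up to 3166 probe sets had an unadjusted limma p under 0.05.

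A second pattern is the set of probe sets called between vte2 and WT at day 3. A difference in growth stage as the whole cause of the set is argued against. Of the 372 called probe sets, 46.8% moved the same way between the days in vte1 (44.0% of those not called). That lies within the range around an even split that was set beforehand, but the share cannot exclude stage for part of the set. GSTU25, UGT73B4, UGT76E12, UPOX and AT2G04400, higher in vte2, fell between the days in WT, while AT2G29500, also higher in vte2, rose (2.02). With replicate 3 of all groups left out there were 1200 calls, 350 of the 372 among them, so that these 350 did not need replicate 3. The number of calls rose in every comparison between genotypes without replicate 3, so that it does not decide on replicate 3 as a cause. The array scaling as the whole cause is argued against by 390 calls after quantile normalization, 325 of the 372 among them, although the lower photosynthesis genes within the set did depend on the scaling. None of these causes was excluded for part of the set. An effect of the vte2 genotype is a candidate explanation, found and tested on the same data. How far the loss of tocopherols, which both mutants share, accounts for the set stays open. The vte1 count at day 3 was 48, or 1906 with replicate 3 of all groups left out. AT4G12490 and PDF1.4 were higher in vte2 than in vte1 by 6.88 and 6.69. The 10 splits are too few for a share under 0.05. The real one, 1 of 10, called 261 and the highest other 0 (up to 1521 at an unadjusted limma p under 0.05).

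For the other comparisons of 3 arrays with 3, the 10 splits are likewise too few for a share under 0.05, and the real split called the most in each. It called 2 for vte2 against WT at day 1, 102 and 870 between the mutants at day 1 and day 3, and 7273, 7880 and 6300 between the days in WT, vte1 and vte2, with 0 for the highest other in each of these 6. For vte1 against WT at day 3 it called 19, and the highest other called 15. In those 6, other splits had up to 2909, 3462, 971, 442, 490 and 708 probe sets at an unadjusted limma p under 0.05.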

How the results depend on the processing

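The settings that leave out replicate 1, 2 or 3 of all groups and the simulation with the replicate block were added after the data were seen; the other alternatives were planned and all were run. Numbers of called probe sets moved most with what was assumed about the replicates. They are given in the order vte1 against WT, vte2 against WT and vte2 against vte1 at day 1, the same 3 at day 3, and the vte1 and vte2 interactions, with 333, 15, 831, 48, 372, 560, 168 and 32 in the main setting. The replicate number as a block gave 754, 31, 1709, 259, 834, 1270, 614 and 71. Array weights gave 3639, 87, 4731, 1548, 1026, 2857, 2685 and 274. With replicate 3 left out of all groups there were 2148, 72, 2923, 1906, 1200, 2229, 2142 and 316. With replicate 2 left out there were 0, 0, 49, 0, 40, 33, 0 and 1, and with replicate 1 left out 0, 2, 102, 0, 43, 29, 0 and 0. Where limma called 0, 276 to 850 probe sets had an unadjusted p under 0.05. Between the days, replicate 2 left out gave 4648 in WT, 5566 in vte1 and 3022 in vte2, and replicate 1 left out 4776 in WT and 3384 in vte2. An adjusted p under 0.01 left 117, 6, 357, 5, 142, 213, 12 and 3. The fit on the arrays of the contrast alone, which has fewer arrays to estimate the spread, gave 17, 2, 102, 19 and 870 for the first 4 and the sixth, and 14 for the vte2 interaction. The count for vte1 against WT at day 3 was 95 after quantile normalization, 93 after median centring, 118 with the pseudocount of 88 and 24 without the trend. The pseudocount of 88 also gave 876 between the mutants at day 3 and 65 for the vte2 interaction, which had 14 with the pseudocount of 5.5 and 20 with the stricter filter. The cause was not tested for these changes.

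Leaving out 1 array gave 106 to 1061, 5 to 18, 370 to 1854, 2 to 337, 177 to 294 and 246 to 594 calls for the 6 comparisons between genotypes. Each array whose removal moved such a count by a large factor is named with its value in the results. For the vte1 interaction the range was 33 (without WT replicate 2 of day 3) to 637 (without vte1 replicate 3 of day 1), and 374 without WT replicate 3 of day 3. For the vte2 interaction it was 6 (without WT replicate 2 of day 3) to 43 (without vte2 replicate 3 of day 1). Where the replicate numbers did not pair the arrays, the block moved the counts for vte1 against WT at day 3 and between the mutants at day 3 to 259 and 1270, and deviations of same-numbered arrays there correlated at 0.05, -0.01 and 0.07 and at 0.06, 0.03 and 0.13, with 4 and 3 of 6 arrays closest to their own number. Between the days the block gave 8842, 9684 and 7883, with 2, 3 and 5 of 6. The block kept 332 of the 333 calls for vte1 at day 1 and every call of the other 5 comparisons between genotypes. Scaling moved the split of the vte1 interaction from 83.9% higher to 76.5% (quantile) and 69.4% (median).

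Of 246 values of named genes, 3213 of 3862 alternatives left direction and side of the threshold unchanged and 639 lost the call, 417 of them among 1476 with 1 array left out and 92 with only the arrays of the contrast. No called gene changed direction. Genes chosen with all 3 values of one group beyond all 3 of the other could not do so with 1 array left out. Of genes not called, DFR in vte2 against WT at day 3 turned to -0.15 with array weights, and UF3GT to 0.03 with the pseudocount of 88, to 0.09 without WT replicate 1 to 0.55 without vte2 replicate 2 and, its direction as before, to -0.56 without vte2 replicate 3. Of 69 calls of lists, 9 held with an estimated correlation: heat shock and chaperones in vte1 at day 3 and in the vte1 interaction, both detoxification lists, the wider photosynthesis list and the glycosyltransferases in vte2 at day 3, and the wider photosynthesis list in the vte2 interaction. The calls kept were 61 with quantile normalization, 68 with median centring, 66 with the block, 62 with array weights, 59 with the stricter filter and 423 of 468 with 1 array left out. The ribosomal protein list in vte2 at day 1 changed direction without vte2 replicate 3 (median 0.01, adjusted p = 0.79, from -0.18), while leaving out single arrays gave -0.29 at the lowest (without WT replicate 3 or vte2 replicate 2). The block ended the calls of the chaperone list in vte2 at day 1 (adjusted p = 0.054), the glutathione transferases in vte1 at day 3 (0.053) and the antioxidant list between the mutants at day 3 (0.061). The correlation of the mutants' changes stayed within its jackknife error in all 32 alternatives. That error was computed from the alternatives with 1 array left out, so these could hardly fall outside it. Because the error was wide, the result says little on how stable the correlation is. Single genes and lists were not computed with a replicate left out of all groups. Signals near background limit the dim genes, whose fold changes depend on the pseudocount.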

Other observations

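The test of direction at day 1 in this part was chosen after the day 3 result was seen. The list of 63 cytosolic ribosomal protein genes had a median of 0.26 in vte1 against WT at day 1 (61 above and 2 below 0, 1 called higher, adjusted p = 8e-09, and 0.64 with an estimated correlation). In vte2 it had one of -0.18 (8 above and 55 below 0, none called, adjusted p = 2.6e-05, and 0.52 with an estimated correlation). The vte1 median was 0.12 after quantile normalization and 0.17 without WT replicate 3. The vte2 median was 0.01 without vte2 replicate 3 (adjusted p = 0.79), -0.08 without WT replicate 1, and -0.29 without WT replicate 3 or vte2 replicate 2. The 68 measured plastid-encoded genes had a median of -0.40 in vte1 at day 1 (1 called lower, adjusted p = 1.1e-05, and 0.56 with an estimated correlation) and of -0.45 in vte2 at day 3 (none called, adjusted p = 4.8e-08, and 0.19 with an estimated correlation), where quantile normalization gave -0.31. The vte1 median of these plastid-encoded genes was -0.68 with array weights, -0.19 without vte1 replicate 2 and -0.26 without WT replicate 3. Between the days in WT 45 of the 68 rose and 1 fell (median 1.47, adjusted p = 3.5e-08, and 0.37 with an estimated correlation), with psbA, for a photosystem II reaction centre protein, going from 534 ± 159 to 9012 ± 1067. Of the 11 cytochrome P450 genes 6 rose between the days in WT and none fell (median 0.81, adjusted p = 0.018, and 0.42 with an estimated correlation; 0.52 after quantile normalization, and a call lost without the filter and with the stricter one, adjusted p = 0.052 and 0.15), and of 11 glutathione transferase genes 3 rose and 3 fell (median -0.03, adjusted p = 0.99). With no member called, the glutathione transferase list had a median of 0.30 in vte2 at day 1 (adjusted p = 0.0065, and 0.19 with an estimated correlation), a call lost without vte2 replicate 2 (0.075). In vte1 at day 3 its median was 0.47 (adjusted p = 0.029, and 0.20 with an estimated correlation), a call lost, among others, with the block (0.053) and without WT replicate 1 or 2 or vte1 replicate 2 (0.082, 0.19 and 0.10). The list of 7 xyloglucan endotransglucosylases had a median of 0.51 there with none called (adjusted p = 0.029, and 0.30 with an estimated correlation), a call lost without WT replicate 1 or 2 or vte1 replicate 3 (0.17, 0.19 and 0.086). In vte2 at day 3, CYP71B6 rose from 1161 ± 174 to 2523 ± 347 (1.11 ± 0.20, adjusted p = 0.0048). The cell wall genes EXPA4 and XTH19 rose by 1.45 ± 0.30 and 1.60, in an expansin list of 12 with 2 called higher (median -0.09, while the test pointed up, adjusted p = 0.57) and a xyloglucan endotransglucosylase list of 7 with 1 called higher (median 0.29). Of the 11 LEA and oleosin genes 1 was lower there (median -0.60, adjusted p = 0.12).

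Most of the other genes of the lists fixed before did not pass between vte2 and WT at day 3. NDC1 and AT1G74470 of the tocopherol and prenylquinone list had log2 differences of -0.21 and -0.47 (adjusted p = 0.87 and 0.65), SAG101 of the salicylic acid list 0.48 (0.57), and PDF1.2 and OPCL1 of the jasmonate list -0.67 and 0.47 (0.60 and 0.55). AUR1 of the cell cycle list had -0.38 (adjusted p = 0.54), and DFR and UF3GT of the flavonoid list 0.61 and -0.06 (0.72 and 0.99). The 3 seed oil genes had a median of 0.43 (adjusted p = 0.38) and the 3 seed storage genes one of -0.50, while their mean was -0.02 and the test pointed up (adjusted p = 0.84). In vte1 at day 1 no antioxidant, detoxification, heat shock or seed oil gene of those lists passed (medians -0.27, -0.18, -0.26 and -0.06; adjusted p = 0.53, 0.90, 0.72 and 0.95).

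A hypothesis is that the vte2 difference seen at day 3 had begun by day 1. Of the 372 probe sets called between vte2 and WT at day 3, 74.2% differed in the same direction at day 1, on arrays that are not part of the day 3 comparison, against 59.4% for vte1 against WT at day 1. Both day 1 comparisons use the same WT arrays, and the vte2 share among probe sets not called was not computed. Also, 11 of the 15 day 1 calls were called again at day 3 with the same sign, where 0.25 would be for independent lists. This is consistent with an early start of the response for part of the genes, although AT4G12490 and AT1G65500 were near WT at day 1 (-0.24 and 0.19). For vte1, 1 of the 333 day 1 calls recurred with the same sign at day 3 (0.722 for independent lists), and the changes at both days correlated with r = -0.06 across probe sets, against 0.221 in vte2.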
